A study of Mus musculus with 6 samples.

How the data were processed

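Total RNA from heart ventricle tissue of 6 mice was labelled with biotin and hybridised to 1-colour Affymetrix-type expression arrays, 1 array per mouse. All 6 mice were on a Rag2 knockout background, in which mature T and B lymphocytes do not form; 3 carried wild-type Trex1 (Trex1 WT) and 3 were Trex1 knockouts (Trex1 KO). The values were taken from the series' table of 45101 probe sets, of which 64 were array controls and 45037 were not. The deposited values are the authors' summarised intensity of each probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. In the table, the mean of each array after trimming the lowest and highest 2% of values was 500.0, so the arrays had been scaled to a common level before deposit and were not normalised again. Signals ran from 0.109 to 58127. No scanner images, probe-level values or detection calls were analysed here.

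Groups were taken from the sample titles. The series' design text pairs the animals by number as littermates, and the letters A, B and C in the titles follow those pairs. The pairing was checked before any calls were compared: the deviations from the group means correlated at 0.151, 0.192 and 0.147 within littermate pairs and between -0.161 and 0.0101 for the other Trex1 WT and Trex1 KO combinations. These are correlations across probe sets, which are not independent replicates. The littermate pair was used as a block in an alternative fit, chosen along with the main design before the data were examined. Spearman correlations between arrays across probe sets lay between 0.917 and 0.934.

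Each value was transformed to log2(signal + 16). Probe sets were tested when their mean over the 6 arrays reached the 40th percentile of all probe sets that were not controls (a log2 value of 6.13, or a signal of 53.8), which left 27022. Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, over 3 Trex1 WT and 3 Trex1 KO arrays with 4 residual degrees of freedom (2 with the block), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. All tests were two-sided. Log2 differences are Trex1 KO minus Trex1 WT, and folds are on the log2(signal + 16) scale, which understates changes of dim probe sets. Signals are given as means ± SD. The 27 bacterial and phage control probe sets, which have no counterpart in the tissue, had a median signal of 8.98 and reached 69.8 at most. Between 55.4% and 58.3% of the other probe sets lay above that highest value on each array. The precision of all values is limited by the number of arrays.

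Gene symbols came from the platform's annotation, updated through Entrez identifiers with a RefSeq gene table of the assembly GRCm38.p6. A single symbol was given for 34945 probe sets, several for 932 and none for 9160; 34741 were matched by identifier, and 0 symbols changed. The files name no genome build, so the gene table was used only for names and for the order of genes along chromosomes. For each gene, the brightest of its probe sets with a single symbol stood for it, and disagreement with its other probe sets is stated where it occurred. Of 18193 genes with such a probe set, 12811 were tested.

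There were 23 gene lists, fixed from general knowledge before the data were examined. Those of immune function were interferon-stimulated genes, nucleic acid sensing and metabolism, interferons and their receptors, MHC class I and class II presentation, and inflammatory cytokines and chemokines. Those of immune cells were markers of monocytes and macrophages, natural killer cells, neutrophils and T and B lymphocytes. Those of the heart and of general processes were cardiomyocyte structure and calcium handling, cardiac stress and fetal genes, fibrosis and extracellular matrix, fatty acid oxidation, oxidative phosphorylation, endothelial markers, p53 targets, cell cycle genes and immediate early genes. The last were adipose, erythroid, skeletal muscle and atrial markers. Lists with at least 3 tested members (22 of them) were tested with limma's camera with a preset inter-gene correlation of 0.01. Adjusted p-values of lists are Benjamini-Hochberg values over these 22, and an estimated correlation was the alternative. Counts of list members past the threshold are given after adjustment over all probe sets and adjusted over the list alone.

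The named genes followed a rule fixed before the data were examined. It took Trex1 and Rag2, and in each direction the 15 genes with the largest difference among those past the threshold and changed the same way in all 3 littermate pairs. Where fewer than 10 passed, the genes with the smallest unadjusted p followed, up to 10. From each list it took the 3 largest members that passed, or the member with the smallest p. Sex-linked genes were kept out of the ranking. Probe sets with several symbols gave no named gene, except the probe set of the deleted gene. Genes named outside the rule are said to be so.

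RNA quality was described by the 3' to 5' signal ratios of the control probe sets of Actb and Gapdh and by the signal of the 18S ribosomal RNA control, compared with exact permutation tests. The tests were tried on simulated data for this comparison, with 20 simulations of 27022 probe sets of which 200 were changed. With variances drawn from the fitted prior, limma recovered 82.9% of probe sets changed by 2 on the log2 scale and 42.8% of those changed by 1, and 5.92% of its calls were false. With each probe set's own variance, as moderated by eBayes, it recovered 91.6% and 56.8%, and 8.48% of the calls were false. With littermate pairs as a block, the recovered shares were 78.7% and 35.7% with prior variances (5.73% of calls false) and 90% and 54.2% with own variances (11.0% false). No difference between littermate pairs was simulated, so these shares do not show what a block gains where pairs differ. Lists of 20 among 12811 genes were simulated, and 0.5 on the log2 scale was the only shift tried. With all members shifted by that much, camera called 20 of 20 lists with either correlation. Of 200 unshifted lists it gave an unadjusted p under 0.05 for 8 with the preset correlation and 3 with the estimated one. The simulated genes varied independently of each other. In the data, the estimated correlation was 0.44 for the interferon-stimulated genes and 0.83 for the MHC class II genes. These rates therefore cannot show whether the preset correlation of 0.01 holds for the real lists.

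Alternatives were another pseudocount (1 or 64), quantile normalisation, median centring, no filter or a filter at the 60th percentile, eBayes without a trend or with robust priors, array weights, a threshold of 0.10, the littermate pair as a fixed or random block, the mean of all probe sets of a gene, a 1.5-fold criterion, and leaving out each array or pair. Leaving out the arrays Trex1 WT A and Trex1 WT B together, and the Actb 3' to 5' ratio as a covariate, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.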

Results

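The arrays measured transcripts in the heart ventricles of 3 Trex1 WT and 3 Trex1 KO mice, all lacking Rag2, as 3 pairs of littermates (A, B and C), each with 1 Trex1 WT and 1 Trex1 KO animal. Trex1 is the major DNA exonuclease of mammalian cells and degrades DNA in the cytosol, and Rag2 is needed to assemble the antigen receptor genes of T and B cells. The comparison asks which transcripts differ in the heart when Trex1 is missing, in animals without an adaptive immune system. Sex was matched within pairs. The Y-linked transcript Eif2s3y had signals of 2571 and 2138 in the Trex1 WT and Trex1 KO animals of pair A, 2513 and 2146 in pair B, and 6.6 and 47.3 in pair C. Xist had signals of 6747 and 7569 in pair C and at most 119 in pairs A and B. RNA quality differed on some arrays. The Actb 3' to 5' ratio was 2.09, 2.29 and 1.80 in Trex1 WT A, B and C and 1.66, 1.6 and 1.68 in the Trex1 KO animals, which did not overlap. The exact permutation p was 0.1 (two-sided), the smallest that 3 arrays against 3 can give. The Gapdh ratio was 0.893 ± 0.0387 in Trex1 WT and 0.858 ± 0.0236 in Trex1 KO (SD, n = 3, exact permutation p = 0.2). The 18S signal was 12811, 13708 and 924 in Trex1 WT A, B and C and 2834, 1907 and 798 in their Trex1 KO littermates (exact permutation p = 0.3 on the log2 scale). The littermates of pair C lay closest together.

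The Trex1 transcript was nearly lost in all 3 knockout hearts. Its probe set gave signals of 714, 340 and 887 in Trex1 WT A, B and C and of 9.45, 20.6 and 34.2 in Trex1 KO A, B and C, the latter below the highest bacterial control. The difference was -4.10 on the log2 scale (SE 0.38, limma, Benjamini-Hochberg adjusted p = 0.00109). The platform annotation assigns this probe set to Atrip and Trex1 together, and the transcript it was designed on belongs to Trex1. Whether it lies in the deleted part of the gene is not given in the sources used here. The separate probe set of Atrip, a partner of the checkpoint kinase ATR, had signals of 192 ± 39.4 and 181 ± 15.6 (adjusted p = 0.988 in limma). Without both animals of pair A, the Trex1 difference was -3.73 with an adjusted p of 0.0748 in limma. Rag2, disrupted in every animal, had signals near background of 51.5 ± 38.8 in Trex1 WT and 76.2 ± 18.7 in Trex1 KO (log2 difference 0.66, SE 0.51, limma adjusted p = 0.955).

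Loss of Trex1 went with higher levels of a small set of transcripts, most of them induced by interferon, and lower levels of a few others. Among 27022 probe sets, 59 were higher and 7 lower in Trex1 KO (limma, Benjamini-Hochberg adjusted p under 0.05), each in the same direction in all 3 littermate pairs. They included 49 higher and 6 lower probe sets of a single gene, 9 and 1 of several genes, and 1 higher probe set with no gene named. Taking the brightest probe set per gene, 40 genes rose and 5 fell (68 and 12 with littermate pairs as a block). Of the 40, 23 were members of the interferon-stimulated list, 4 of the nucleic acid sensing list and 13 of none of the lists. These counts give list membership only. Genes outside the first list, such as Ifi27, can be interferon-inducible too, so 23 is not the full number of such genes. At least a 2-fold difference in the same direction in all 3 pairs was seen for 59 probe sets that were higher and 9 that were lower, of which 47 and 3 also passed the test. Chance alone gives the same sign in all 3 pairs for 25% of probe sets. The 3 Trex1 KO arrays lay all above or all below the 3 Trex1 WT arrays for 1506 and 1349 probe sets, 10.6% of those tested, where chance gives 10%. With littermate pairs as a block, 105 probe sets rose and 16 fell, and all 66 of the unblocked calls were among them. The number of higher probe sets was 33 without Trex1 KO B and 38 without Trex1 KO C, and the number of lower ones was 4 without Trex1 WT A and 3 without Trex1 KO A. The counts were 8 and 1 with the Actb ratio, which separated the groups, as a covariate. The p-values measure the spread between these 6 animals, each hybridised once.

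Interferon-stimulated genes rose as a group. Of 37 tested members of the list, 23 rose and 0 fell after adjustment over all probe sets (34 and 0 adjusted over the list alone). The median difference was 1.24 on the log2 scale, with medians of 1.26, 1.41 and 1.25 in pairs A, B and C. Usp18, which removes ISG15 from proteins and restrains interferon receptor signalling, rose 10.1-fold, from 650 ± 127 to 6660 ± 666 (log2 difference 3.34, SE 0.15, limma adjusted p = 6.54e-06). Oas3, which makes the oligoadenylates that activate RNase L, rose from 27.2 ± 2.62 to 282 ± 47.1, with a log2 difference of 2.78 and a limma adjusted p of 0.00109. The lower signals of Oas3, and of Mx2 below, lay under the highest bacterial control, and their differences were 1.91 and 1.37 with a pseudocount of 64. Ifit1, an antiviral RNA-binding protein, rose from 755 ± 251 to 4775 ± 809 (log2 2.67, limma adjusted p = 0.000354), and its relatives Ifit3 and Ifit2 rose 6.06-fold and 4.19-fold (limma adjusted p = 4.75e-05 and 0.000574). Irf7, the transcription factor that drives interferon alpha genes, rose 5.94-fold from 667 ± 124 to 4140 ± 1362 (limma adjusted p = 0.000728). Oasl1 rose 4.82-fold and Lgals3bp, a secreted glycoprotein, 4.26-fold (limma adjusted p = 0.00524 and 9.88e-05). Mx2, an antiviral GTPase, rose from 26.9 ± 12.2 to 172 ± 37.0 (limma adjusted p = 0.0306). It lost its call without any of the 3 Trex1 KO arrays or Trex1 WT C (limma adjusted p up to 0.243). The 2 members below 0, named after their values were seen, were the interferon-inducible GTPases Igtp and Iigp1, with log2 differences of -0.58 and -0.31 that did not pass. The camera test gave the list an adjusted p of 6.06e-92 in limma, and adjusted p = 0.091 with an estimated correlation. The count of 23 was 31 with littermate pairs as a block, 10 in eBayes without an intensity trend and 5 with the Actb ratio as a covariate. The Actb ratio and the 18S signal moved with the groups here too. The log2 difference in 18S signal between littermates was -2.18, -2.85 and -0.21 in pairs A, B and C.

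Other strongly raised genes lay outside that list. Slfn4, a member of the Schlafen family, rose 12.0-fold, from 61.3 ± 18.9, near the highest bacterial control, to 921 ± 259 (log2 3.59, SE 0.25, limma adjusted p = 0.000182). Its difference was 2.95 with a pseudocount of 64, where that of Usp18 was 3.25. Ifi27, an interferon-inducible gene, rose 9.50-fold from 1904 ± 307 to 18209 ± 2737 (log2 3.25, SE 0.14, limma adjusted p = 6.54e-06). Plac8 rose 7.01-fold, from 206 ± 48.0 to 1567 ± 460 (limma adjusted p = 0.000679). Cfb, factor B of the alternative complement pathway, rose 6.90-fold, from 95.6 ± 42.8 to 729 ± 162 (limma adjusted p = 0.00188). Trim30d, of the tripartite motif family, rose 4.04-fold (limma adjusted p = 0.000574). Its other tested probe set gave a log2 difference of 1.80 and did not pass (limma adjusted p = 0.0515). Of the other genes in no list, named after their values were seen, Gm4951 rose by 1.90, the lipocalin Apod by 1.77, Ifi213 by 1.71, Ncoa7 by 1.34, Trim34a by 1.20, Rnf213 by 1.06, Parp9 by 0.80 and Parp12 by 0.79 on the log2 scale (limma adjusted p up to 0.0483).

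**Figure D1:**
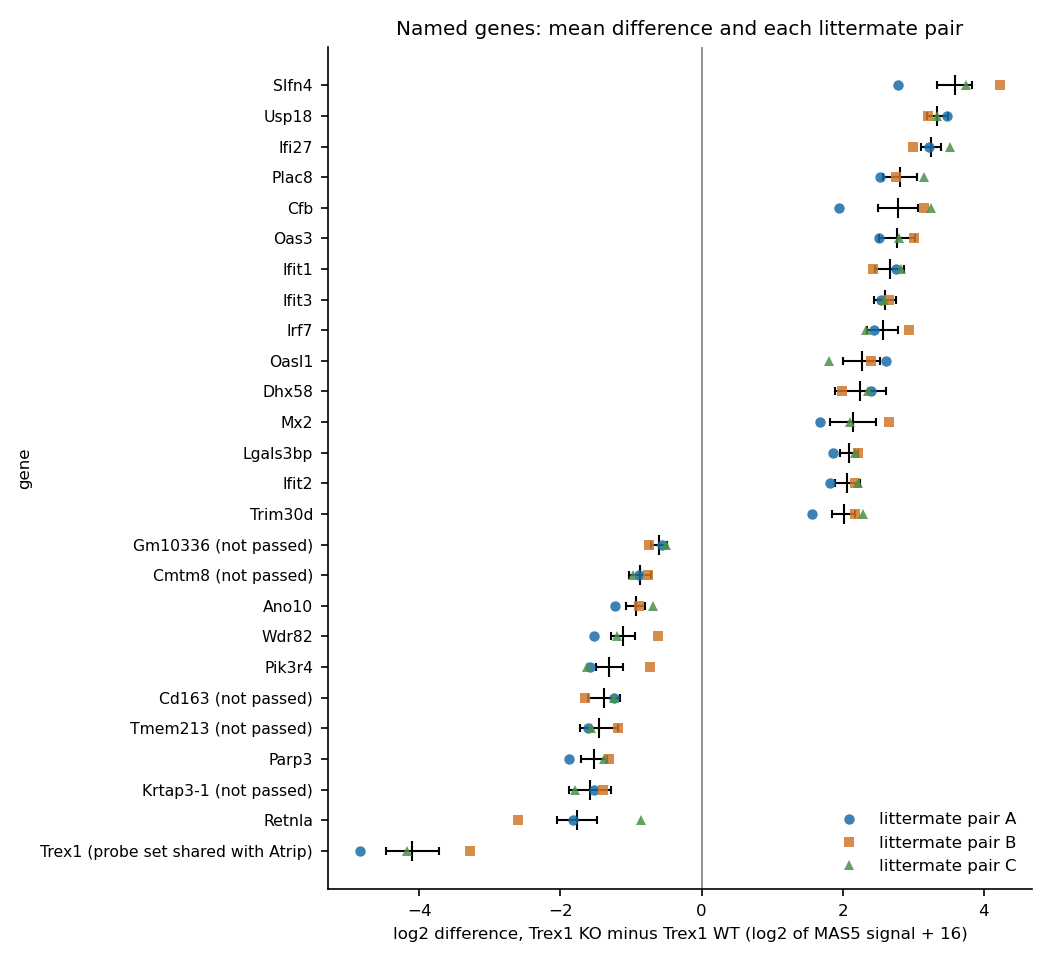
Log2 differences between Trex1 KO and Trex1 WT (horizontal axis, on log2 of the signal + 16) of the named genes, with the mean difference (tick), its SE from limma (bar) and each littermate pair A, B and C as a point. In every pair Usp18 lay between 3.21 and 3.48, and Retnla ran from -2.61 in pair B to -0.86 in pair C.

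Among genes of nucleic acid sensing and metabolism, the RNA sensors Ifih1 and Ddx58, their regulator Dhx58 and Zbp1 rose and the other 20 did not pass. Of 24 tested members, 4 rose and 0 fell (9 and 0 adjusted over the list alone), and the median difference was 0.21 (0.11 without Trex1 WT C). Ifih1, the RNA sensor MDA5, rose from 636 ± 73.9 to 1872 ± 235 (log2 1.53, SE 0.14, limma adjusted p = 0.000955), and Ddx58, the RNA sensor RIG-I, named after its value was seen, rose by 1.14 (limma adjusted p = 0.00392). Zbp1, a sensor of Z-form nucleic acid, rose from 136 ± 65.3 to 516 ± 78.2 (log2 1.88, limma adjusted p = 0.0256). This call was lost without any single array except Trex1 WT B (limma adjusted p up to 0.156). The other tested probe set of Zbp1 gave 1.64 and did not pass (limma adjusted p = 0.247). Dhx58, a regulator of these RNA sensors, rose from 24.1 ± 15.1, below the highest bacterial control, to 169 ± 41.2 on its brightest probe set (log2 2.25, limma adjusted p = 0.0474), while its other probe sets gave 0.69 and -0.19 and did not pass. The size of this difference depends on the pseudocount (1.40 with 64 and 2.91 with 1, the latter not passing). The call was lost without any single array except Trex1 WT B (limma adjusted p up to 0.316). The DNA sensor Cgas and the DNA-binding Ifi204, both named after their values were seen, had differences of -0.18 and 1.20 and did not pass (limma adjusted p = 0.979 and 0.113). With the block 5 members rose, the added one being Tlr3, named after its value was seen (0.84, limma adjusted p = 0.0350). The camera test in limma gave the list an adjusted p of 2.91e-07, adjusted p = 0.202 with an estimated correlation, and 5.79e-05 with the Actb ratio as a covariate.

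Transcripts of the interferons themselves were near background. Of the list of interferons and receptors, 5 of 11 members were bright enough to test and 0 passed, also when adjusted over the list alone. The median difference was 0.00, and the camera test in limma gave an adjusted p of 0.662 (adjusted p = 0.761 with an estimated correlation). Ifnb1, named after its value was seen, had mean signals of 75.6 in Trex1 WT and 74.9 in Trex1 KO, close to the highest bacterial control. Ifng and the 5 interferon alpha genes of the list lay below the filter. The receptor subunit Ifngr2 had a log2 difference of 0.11 (limma adjusted p = 0.959). At such signals a change can be missed.

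The genes that fell were few, and most lay on the chromosome of Trex1. Parp3, an ADP-ribosyltransferase that acts at DNA breaks, fell from 2056 ± 549 to 691 ± 64.4 (log2 difference -1.52, SE 0.18, limma adjusted p = 0.00566); its other probe sets gave -0.88 and -1.04 and did not pass. Pik3r4, the regulatory subunit of the class III phosphatidylinositol kinase, fell from 621 ± 126 to 240 ± 38.4 (log2 -1.31, limma adjusted p = 0.0256). Wdr82, a subunit of the SET1 histone methyltransferase complexes, fell from 1341 ± 248 to 607 ± 83.5 (log2 -1.11, limma adjusted p = 0.0274), and Ano10, of the anoctamin family, from 2600 ± 368 to 1353 ± 173 (log2 -0.93, limma adjusted p = 0.0251). Retnla, a secreted product of alternatively activated macrophages, fell from 2007 ± 399 to 618 ± 310 (log2 -1.76, SE 0.28, limma adjusted p = 0.0459). Of the 5 genes, only Parp3 kept its call without each single array. Pik3r4 lost it without Trex1 WT A or C or Trex1 KO A or C (limma adjusted p up to 0.161), Wdr82 without any array except Trex1 WT B (up to 0.164). Ano10 lost it without Trex1 WT A or C or Trex1 KO A or B (limma adjusted p up to 0.145), and Retnla without any array except Trex1 KO C (up to 0.200). In eBayes without an intensity trend 0 of the 5 passed (limma adjusted p from 0.126 to 0.396), and the differences are those above, since only the spread is estimated anew. With the Actb ratio as a covariate 0 passed as well (limma adjusted p from 0.106 to 0.796). The log2 differences were then -1.67, -1.84, -1.50 and -0.94 for Parp3, Pik3r4, Wdr82 and Ano10 and -1.20 for Retnla. A dimmer probe set of Alas1, the rate-limiting enzyme of heme synthesis, named after its value was seen, fell from 849 ± 23 to 307 ± 39.5 (log2 -1.43, limma adjusted p = 0.00188), whereas its brightest gave 6052 ± 780 and 6129 ± 681 (limma adjusted p = 0.995). In the gene table of assembly GRCm38.p6, 4 of the 5 genes that fell lay on the chromosome of Trex1, which held 5.62% of the tested genes with a position. All 4 lay within 100 tested genes of it, and none within 50.

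**Figure D2:**
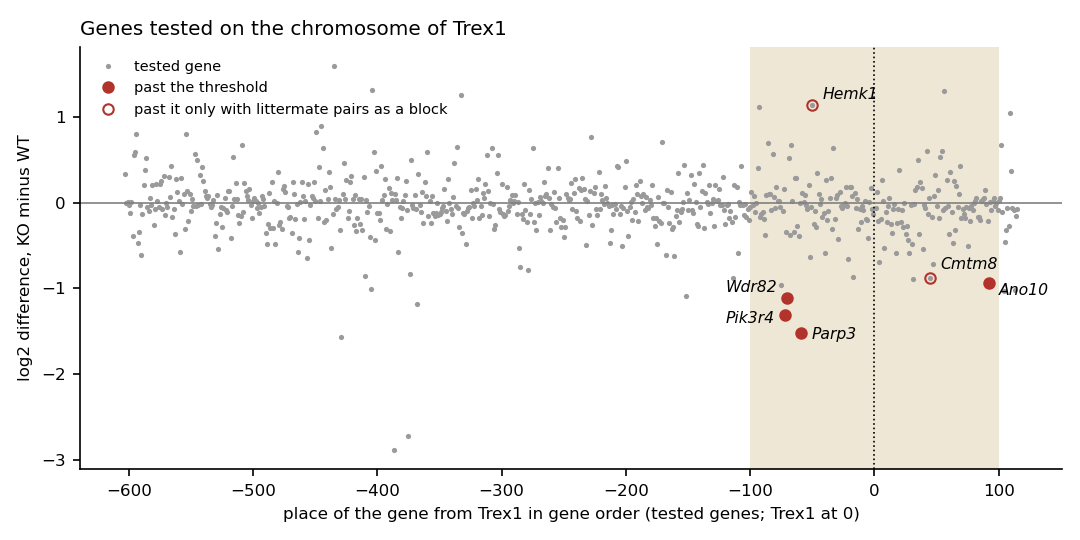
Log2 difference between Trex1 KO and Trex1 WT (vertical axis) of the 718 tested genes on the chromosome of Trex1, placed by their order in tested genes from Trex1 (horizontal axis), with the 100 tested genes on each side shaded and genes past the threshold in red. The genes that fell, Pik3r4, Wdr82, Parp3 and Ano10, lay at -72, -70, -59 and 92.

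The next lowest genes by p did not pass without the block. Cd163, a scavenger receptor of macrophages for haemoglobin and haptoglobin, had signals of 518 ± 160 and 185 ± 29.0 (log2 difference -1.38, limma adjusted p = 0.0504), with adjusted p-values of 0.00855 with littermate pairs as a block and 0.0260 without Trex1 WT C. In pair C its difference was -1.24. Cmtm8 had signals of 612 ± 70.6 and 326 ± 38.8 (log2 -0.88, limma adjusted p = 0.0772, and 0.0306 with the block). Gm10336 had a log2 difference of -0.60 (limma adjusted p = 0.0817, and 0.0371 with the block). Krtap3-1 and Tmem213 had log2 differences of -1.57 and -1.45 (limma adjusted p = 0.105 and 0.106).

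Antigen presentation genes were ranked in opposite directions by class. In the MHC class I list 0 of 12 tested members passed (4 higher and 0 lower adjusted over the list alone) and the median was 0.31. The camera test in limma ranked the list higher with an adjusted p of 1.64e-05 (adjusted p = 0.309 with an estimated correlation). Its medians were 0.05, 0.10 and 0.66 in pairs A, B and C, and its limma camera adjusted p was 0.126 without pair C. The median was 0.11 without Trex1 WT C and 0.73 with the Actb ratio as a covariate (limma camera adjusted p = 0.0359 and 1.08e-10). H2-K1, a classical class I heavy chain, had signals of 14302 ± 3333 and 21843 ± 2916 (log2 0.63, limma adjusted p = 0.418, and 0.0306 without Trex1 WT B). In the MHC class II list 0 of 8 tested members passed (0 higher and 5 lower adjusted over the list alone) and the median was -0.67, with -0.65, -0.89 and -0.41 in pairs A, B and C and -0.39 without Trex1 WT B. Camera ranked the list lower with an adjusted p of 5.87e-05 in limma (adjusted p = 0.306 with an estimated correlation). With the Actb ratio, which moved with the groups, as a covariate, the class II median was -0.15 (limma camera adjusted p = 0.912). H2-Ab1, a class II beta chain, had signals of 2137 ± 734 and 1082 ± 283 (log2 -0.95, limma adjusted p = 0.405, and 0.0321 with littermate pairs as a block). With the block 4 members fell. The others, named after their values were seen, were Cd74 (-0.84), H2-Eb1 (-0.79) and H2-Aa (-0.72), with limma adjusted p-values of 0.00385, 0.00537 and 0.00751 in that fit. In pair C, Cd74 and H2-Eb1 had differences of -0.67 and -0.69.

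Chemokines and markers of innate immune cells were ranked higher as groups, with 0 members of any of these lists past the threshold over all probe sets. Of 15 tested cytokines and chemokines, 1 was higher and 0 lower adjusted over the list alone. The median was 0.48, and 0.29 without Trex1 KO B (limma camera adjusted p = 5.10e-06, and adjusted p = 0.277 with an estimated correlation). Cxcl10, an interferon-induced chemokine, had signals of 134 ± 59.9 and 441 ± 205 (log2 1.58, limma adjusted p = 0.261, and 0.0137 with the block), and Cxcl9, named after its value was seen, had a difference of 0.99 (0.0151 with the block in limma). The 24 monocyte and macrophage markers had a median of 0.25, with 2 higher and 1 lower adjusted over the list alone. Their limma camera adjusted p was 0.000147, and adjusted p = 0.553 with an estimated correlation. Without Trex1 KO B and without Trex1 WT C, the limma camera adjusted p was 0.173 and 0.200. The median ran from 0.075 without Trex1 KO B to 0.48 without Trex1 WT B, and was 0.15, 0.14 and 0.39 without Trex1 WT A, Trex1 WT C and Trex1 KO A. With the block Ms4a7, named after its value was seen, rose by 1.02 and Cd163 fell (limma adjusted p = 0.0321 and 0.00855). The 10 tested natural killer cell markers had a median of 0.58 (0.25 without Trex1 KO B) and 0 passed adjusted over the list alone. Their limma camera adjusted p was 0.00103 (adjusted p = 0.306 with an estimated correlation, and 0.134 without Trex1 KO B with the preset). The protease Gzma had a difference of 0.96 (limma adjusted p = 0.917). Of 13 neutrophil markers 5 were tested and 0 passed adjusted over the list alone, with a median of 0.79 that was -0.36 in pair A and 0.43 without Trex1 KO B. The list was ranked higher (limma camera adjusted p = 0.0217, and adjusted p = 0.306 with an estimated correlation). The neutrophil call was lost without Trex1 KO B, Trex1 KO C or Trex1 WT C (limma camera adjusted p = 0.228, 0.0663 and 0.109) and with array weights (0.0620). The receptor gene Csf3r had a difference of 0.82 (limma adjusted p = 0.901). With the Actb ratio as a covariate, the chemokines and the macrophage markers kept their calls with medians of 0.71 and 0.67 (limma camera adjusted p = 5.79e-05 and 1.08e-10). The natural killer cell and neutrophil lists lost theirs, although their medians of 0.58 and 0.84 were no smaller (limma camera adjusted p = 0.0509 and 0.160). Of 15 T and B lymphocyte markers, 13 had a probe set with a single symbol, and only 2 of these were bright enough to test. These were too few for the list test, and 0 passed, also adjusted over the list alone. Ighm had a difference of -0.34 (limma adjusted p = 0.956).

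**Figure D3:**
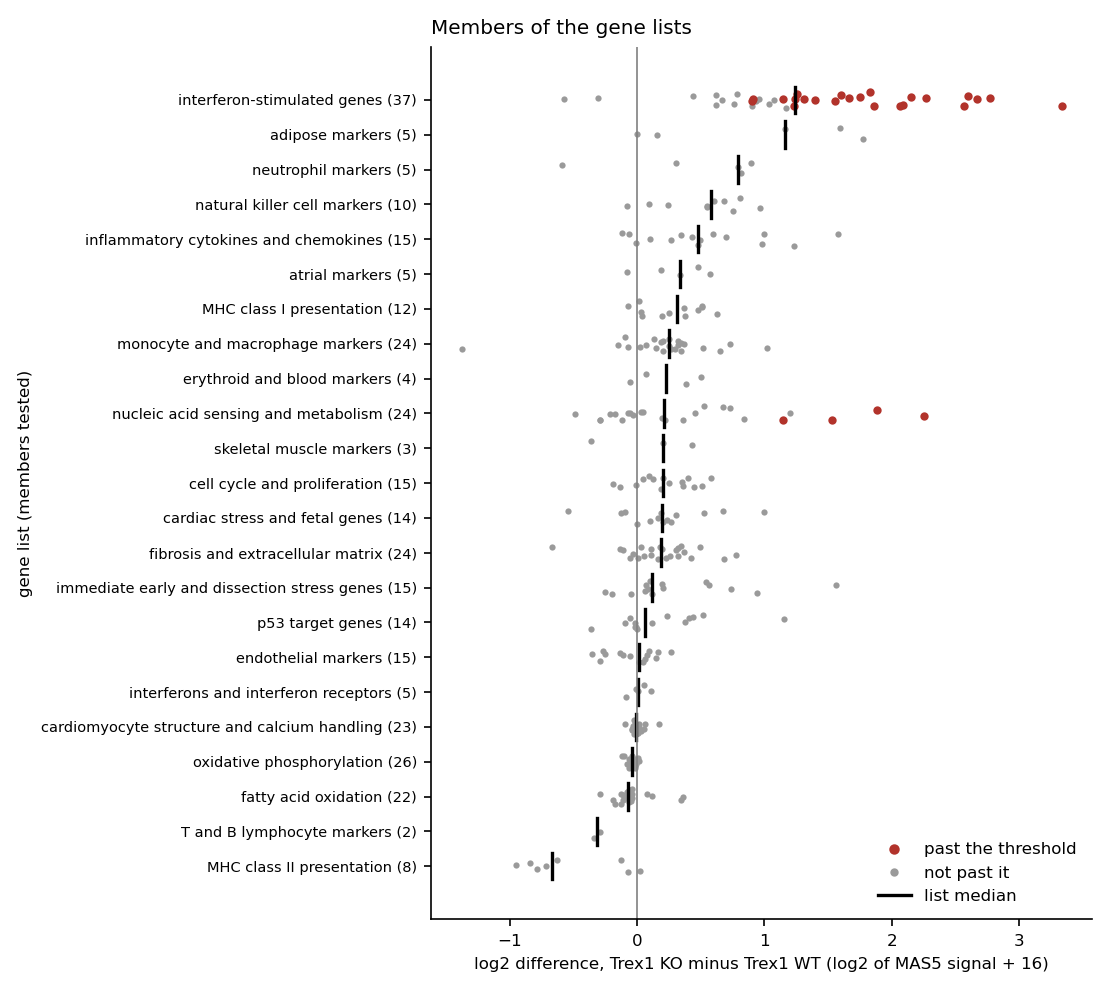
Log2 differences between Trex1 KO and Trex1 WT of the tested members of each gene list (points, red where past the threshold) with the list's median (black bar), over 3 arrays per group. The interferon-stimulated genes have a median of 1.24 and the cardiomyocyte genes one of -0.01.

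Genes of heart muscle gave signals near the top of the scale, and stress and matrix genes were ranked higher as groups. All 23 cardiomyocyte genes were tested and 0 passed, also adjusted over the list alone. Their median was -0.01 and their mean -0.00, while camera ranked them higher with an adjusted p of 0.799 in limma (adjusted p = 0.949 with an estimated correlation). The sarcomere gene Tcap had signals of 28272 ± 3876 and 31723 ± 2629 (limma adjusted p = 0.955). Of the 23, 19 had a mean signal above 0.5 of the lowest array maximum (maxima from 45848 to 58127). Their median differences of 0.15, -0.096 and -0.070 in pairs A, B and C went the way of the log2 ratios of the maxima, 0.17, -0.17 and -0.11. Such signals can hide a change, so neither a change nor its absence is read from this list. Its median was -0.11 without Trex1 WT A (limma camera adjusted p = 0.00185) and 0.07 without Trex1 WT C (0.0280), which has the same limit. Of 14 tested cardiac stress and fetal genes 0 passed (3 higher and 0 lower adjusted over the list alone). The median was 0.20 (0.11 without Trex1 WT A and 0.098 without Trex1 KO B), and the limma camera adjusted p was 5.87e-05 (adjusted p = 0.202 with an estimated correlation). Nppa, the atrial natriuretic peptide gene that ventricles re-express under load, had signals of 16165 ± 4540 and 31458 ± 3918 (log2 0.996, limma adjusted p = 0.126, and 0.00886 with the block). With the block Mt2, a metallothionein named after its value was seen, also rose, by 0.67 (limma adjusted p = 0.0265). Of the 14 stress genes, 3 had mean signals near the top of the scale, Nppa among them, and the other 11 had a median of 0.19. The atrial markers had medians of 0.57, 0.38 and 0.28 in pairs A, B and C. Whether atrial tissue in the samples contributed to the Nppa difference was not tested. Of 24 tested fibrosis and matrix genes 0 passed (1 higher and 0 lower adjusted over the list alone). The median was 0.19 (0.10 without Trex1 KO B), and the limma camera adjusted p was 5.87e-05 (adjusted p = 0.306 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, had signals of 1879 ± 351 and 3009 ± 335 (limma adjusted p = 0.203, and 0.0318 without Trex1 WT B). With the Actb ratio as a covariate the stress list lost its call although its median was no smaller (limma camera adjusted p = 0.0594, median 0.23). The matrix list kept its call (0.0138, median 0.21). The cardiomyocyte list then passed with a median of -0.12 (limma camera adjusted p = 0.0404), under the limit above.

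Metabolic and vascular lists did not pass with the brightest probe set of each gene over all 6 arrays and no covariate. For fatty acid oxidation, 22 members were tested, 0 passed (0 also adjusted over the list alone), and the median was -0.07 (limma camera adjusted p = 0.110, and 0.666 with an estimated correlation). Ech1, of that pathway, had a difference of -0.17 (limma adjusted p = 0.955). For oxidative phosphorylation, 26 members were tested, 0 passed (0 also adjusted over the list alone), and the median was -0.04 (limma camera adjusted p = 0.203, and 0.861 with an estimated correlation). Sdhc, of respiratory complex II, had a difference of -0.12 (limma adjusted p = 0.955). The limma camera adjusted p of fatty acid oxidation was 0.0158 without Trex1 KO C and 0.0320 without Trex1 WT B, but 0.835 without Trex1 KO B and 0.710 without Trex1 WT C, with medians of -0.026 and -0.038. That of oxidative phosphorylation was 0.0270 without Trex1 KO C, 1.88e-06 without Trex1 WT A and 0.00816 with the mean of all probe sets of a gene, while its median was 0.010 without Trex1 WT C (0.650). Of the oxidative phosphorylation genes 22 of 26, and of the fatty acid oxidation genes 7 of 22, also lay near the top of the scale. The former had median differences of 0.079, -0.13 and -0.076 in pairs A, B and C, again in the direction of the maxima. The oxidative phosphorylation results are therefore not read as changes in expression. The 7 fatty acid oxidation genes had medians of -0.0014, -0.19 and -0.082, and the other 15 one of -0.061, so this limit does not cover most of that list. Its call depended on the arrays used and on the covariate, so no change is read from it either. For 15 endothelial markers, 0 passed (0 also adjusted over the list alone). The median was 0.02 and the mean -0.04, and camera ranked the list lower with an adjusted p of 0.662 in limma (0.889 with an estimated correlation). The endothelial median ran from -0.10 without Trex1 KO B to 0.073 without Trex1 WT B. Fatty acid oxidation and endothelial markers passed with the Actb ratio as a covariate, with medians of -0.12 and 0.19 (limma camera adjusted p = 0.0404 and 0.0444). Tek, the angiopoietin receptor, had a difference of -0.36 (limma adjusted p = 0.890).

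Targets of p53 and cell cycle genes were ranked higher, with 0 members past the threshold. Of 14 tested p53 targets, 1 was higher and 0 lower adjusted over the list alone. The median was 0.06, and 0.098, 0.092 and 0.11 without Trex1 WT A, Trex1 WT C and Trex1 KO B (limma camera adjusted p = 0.0130, and adjusted p = 0.202 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, had signals of 656 ± 87.2 and 1545 ± 599 (log2 1.15, limma adjusted p = 0.175, 0.0125 with the block and 0.0470 without Trex1 KO C). Of 15 tested cell cycle genes 0 passed adjusted over the list alone. The median was 0.20, and 0.33 without Trex1 KO A (limma camera adjusted p = 0.0130, and adjusted p = 0.306 with an estimated correlation). That call was lost without Trex1 KO B, Trex1 WT A or Trex1 WT C (limma camera adjusted p = 0.134, 0.104 and 0.0523) and without the filter (0.0544). Both p53 targets and cell cycle genes lost their calls with the Actb ratio as a covariate (limma camera adjusted p = 0.154 and 0.0509). Their medians were then 0.048 and 0.19, close to those without it. Mki67, a proliferation marker, had a difference of 0.45 (limma adjusted p = 0.954). The 15 tested immediate early genes had a median of 0.12, from -0.070 without Trex1 KO B to 0.40 without Trex1 WT B, and 0 passed adjusted over the list alone (limma camera adjusted p = 0.0533, 0.0433 with the block, and 0.666 with an estimated correlation). This list passed without Trex1 KO A, Trex1 KO C or Trex1 WT B (limma camera adjusted p = 0.0128, 1.16e-05 and 0.0317), but not without Trex1 KO B (0.435). It also passed with a pseudocount of 64, median centring and array weights (limma camera adjusted p = 0.0462, 0.0356 and 0.0262). Fos had a difference of 0.54 (limma adjusted p = 0.917).

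Markers of other tissues that a dissected ventricle can carry differed between pairs. The 5 tested adipose markers had a median of 1.16, with medians of 0.21, 0.28 and 1.61 in pairs A, B and C, 0.41 without Trex1 WT B and 0.26 without Trex1 KO C. Of them 0 passed, also adjusted over the list alone (limma camera adjusted p = 0.00547, and adjusted p = 0.202 with an estimated correlation). Adipoq, the adiponectin gene, had signals of 29.3 ± 6.48 and 226 ± 280 (log2 1.77, limma adjusted p = 0.823), with a difference of 3.68 in pair C. Its mean signal in Trex1 WT lay below the highest bacterial control, so the sizes of these differences are uncertain. The adipose call was lost with the filter at the 60th percentile and without pair C (limma camera adjusted p = 0.116 and 0.110). With the Actb ratio as a covariate the adipose list lost its call with a median of 0.064, and the erythroid list passed with one of 0.66 (limma camera adjusted p = 0.151 and 0.0404). Of the 4 tested erythroid, 3 skeletal muscle and 5 atrial markers 0 passed, also adjusted over each list alone. Their medians were 0.23, 0.21 and 0.34 (limma camera adjusted p = 0.261, 0.751 and 0.0704, and 0.666, 0.866 and 0.306 with an estimated correlation). The erythroid list passed without Trex1 KO A or Trex1 WT B (limma camera adjusted p = 0.0256 and 0.0359), and the atrial list without Trex1 WT B (0.0359). The erythroid median was -0.084 without Trex1 KO B and 0.090 without Trex1 WT C, and the atrial median 0.17 without Trex1 WT C (limma camera adjusted p = 0.863, 0.933 and 0.200). The skeletal muscle median ran from -0.024 without Trex1 WT C to 0.50 without Trex1 WT B. Alas2 of the erythroid list, Tnni2 of fast skeletal muscle and Nr2f2 of the atrial list had differences of 0.50, -0.36 and 0.48 (limma adjusted p = 0.955, 0.955 and 0.926).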

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

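Leaving out the arrays Trex1 WT A and B together and the Actb ratio as a covariate were chosen after the data were seen. Of 22 named genes that passed, Usp18, Ifi27, Ifit1, Ifit2, Ifit3 and Lgals3bp stayed past the threshold in all 22 settings run for them, and 15 did so without each single array. The cause of the changes below was not tested unless stated.

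The counts of higher and lower probe sets (59 and 7) were 24 and 4 in eBayes without a trend, 95 and 13 with array weights, 105 and 16 with littermate pairs as a block, and 95 and 12 with them as a random block. With weights or either block, all 66 calls were kept. Without Trex1 WT A and B, 62 were higher and 4 lower; with 1 Trex1 WT array left, the spread there comes from the Trex1 KO arrays alone. With the Actb covariate 8 were higher and 1 lower. The ratio separates the groups, so the covariate and the genotype are hard to tell apart in this fit. Calls were lost also where the difference did not shrink. Plac8 and Cfb went from 2.81 and 2.79 to 3.04 and 3.24, with limma adjusted p-values of 0.0720 and 0.0962. Other differences shrank, such as Retnla from -1.76 to -1.20 and Oasl1 from 2.27 to 1.73. The 23 interferon-stimulated genes past the threshold became 31 with the block, 10 without the trend and 5 with the covariate, and of the 22 named genes past the threshold 13 and 6 kept their call without the trend and with the covariate. With an estimated correlation, the interferon-stimulated list kept its median of 1.24 with an adjusted p of 0.091 (camera in limma; from 5.61e-93 to 0.091 over its alternatives), and 0 of the 13 lists passed.

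Leaving out single arrays or pairs gave 23 to 85 higher and 0 to 12 lower probe sets, 9 to 27 interferon-stimulated genes past the threshold, and Trex1 differences from -4.51 to -3.73. Without pair A, whose removal gave the lowest counts (23, 0 and 9), the limma adjusted p of Trex1 was 0.0748, against 0.000141 to 0.0748 over its alternatives. Without Trex1 WT B 85 were higher; without pair C 34 were higher, 4 lower and 11 interferon-stimulated genes passed; without pair B 12 were lower. Leaving out 1 array leaves 3 residual degrees of freedom.

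The numbers of probe sets at least 2-fold different in all pairs (59 higher, 9 lower) were 133 and 53 without the filter and 196 and 42 at 1.5-fold, by construction more. The lower number was 4 with a pseudocount of 64 and 3 with the filter at the 60th percentile. Without an array, over fewer pairs, they were 109 to 164 and 37 to 51.

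Medians near 0 changed sign; ranges here are over single arrays or pairs left out. That of the interferons and receptors was -0.000856 with a pseudocount of 64, -0.012 with quantile normalisation, -0.019 with centring, -0.0090 without the filter and -0.019 as the mean of probe sets. It was -0.055 without Trex1 WT A and B, -0.16 with the covariate, and -0.031 to 0.080 without single arrays or pairs. Cardiomyocyte genes gave 0.017 with quantile normalisation, 0.064 with weights, 0.0076 as the mean of probe sets and -0.11 to 0.068 over these. Endothelial markers gave -0.0063 with centring and -0.10 to 0.073. Oxidative phosphorylation gave 0.026 with weights and -0.12 to 0.010. The erythroid list ran from -0.084 to 0.49, the immediate early list from -0.070 to 0.40 and the skeletal muscle list from -0.11 to 0.50. Without Trex1 WT A and B the medians were outside these ranges: -0.15 for cardiomyocyte genes and for oxidative phosphorylation, 0.14 endothelial, 0.59 erythroid, 0.45 immediate early and 0.57 skeletal muscle. Other lists moved there too. Medians were -0.14 for fatty acid oxidation, 0.29 adipose, 0.58 MHC class I, -0.42 MHC class II, 0.49 macrophage and 0.22 atrial. Over all arrays these were -0.07, 1.16, 0.31, -0.67, 0.25 and 0.34. List p-values without Trex1 WT A and B are not read, since the Trex1 KO arrays alone give the spread. Among genes, Ifngr2 was -0.055 without Trex1 WT A and B and -0.16 with the covariate, Tek 0.052 and Nr2f2 -0.27 with the covariate, and Ighm -0.57 to 0.025 without single arrays or pairs.

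Pairs left out also moved list calls (camera in limma). Without pair A the cardiomyocyte, oxidative phosphorylation, erythroid and immediate early lists passed (adjusted p = 0.0229, 0.000228, 0.0322 and 0.0240), the first 2 with most signals near the top of the scale. Without pair C the immediate early list passed (0.000861), and the neutrophil, macrophage and cell cycle lists did not (0.210, 0.121 and 0.110). The neutrophil list did not pass without pair B (0.273).

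Camera takes neither robust priors nor a random block, so lists were not run with these, and the filter at the 60th percentile was not run for named genes. Signal over background limits the interferon and Rag2 values and the lymphocyte markers below the filter.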

Other observations

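The tests of RNA quality for both patterns below, leukocyte content, the position of genes past the threshold, other probe sets of the same genes and macrophage number were chosen after the results they measure were seen. Mthfd2, Asns and Ddit3, targets of the stress transcription factor ATF4, had higher values, and of their probe sets 1, of Mthfd2, passed. Mthfd2, a mitochondrial folate enzyme, rose on its dimmer probe set from 109 ± 12.8 to 336 ± 52.2 (log2 difference 1.49, limma adjusted p = 0.0147), and its brightest gave 1.97 (0.0568, and 0.00550 with littermate pairs as a block). Asns, asparagine synthetase, had signals of 282 ± 12.5 and 726 ± 223 (log2 1.27, limma adjusted p = 0.0629, 0.0339 with the block and 0.00932 without Trex1 KO A). Ddit3, the stress transcription factor CHOP, had signals of 1069 ± 108 and 2418 ± 730 (log2 1.13, limma adjusted p = 0.0504, 0.00446 with the block and 0.0475 without Trex1 KO A). These 3 genes prompted a test of 25 other ATF4 targets, listed before their values were looked at, as a hypothesis that the integrated stress response may be raised as a group. Their median was 0.12, 18 of 25 lay above 0, 0 passed, and camera in limma gave p = 0.00116 with the preset correlation and p = 0.101 with an estimated one, so the question stays open.

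Over the 10 ways to split the 6 arrays into 3 and 3, 1 split, the real one, gave as many as 66 probe sets past the threshold, and the highest of the other splits gave 0. The 3 other splits that part every littermate pair also gave 0. With 10 splits no share under 0.05 can be reached.

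The rise of interferon-stimulated genes was weighed against RNA quality and cell content. RNA quality as the whole cause is argued against by pair C, whose littermates had close 18S signals and Actb ratios. The list's median there was 0.938 of the mean of pairs A and B (95% interval over resampled genes 0.809 to 1.16). This interval covers the spread between genes, which are not independent, and not that between animals. The contrast rests on 1 littermate pair. With the Actb ratio as a covariate in the fit the median was 1.29, although 5 members then passed. Since the ratio separates the groups, this fit cannot well tell it from the genotype. More leukocytes in the Trex1 KO hearts could add interferon-induced transcripts; the monocyte and macrophage markers had a median of 0.25, below the list's 1.24 (permutation p = 6.00e-05 over genes, which are not independent), but resident macrophages give these markers a high baseline, so a small number of strongly stimulated cells stays open. The rise went with the Trex1 genotype in each littermate pair, with 35, 35 and 37 of 37 members higher in pairs A, B and C. More leukocytes could themselves follow from the genotype. Whether the loss of Trex1 itself or DNA linked to the knockout allele is the cause, and through which cells, stays open.

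Genes that fell lay near Trex1 in gene order, a pattern that DNA from another strain kept around the knockout allele could give. Within 100 tested genes of Trex1, 4 of 199 genes fell, against 1 of 12583 elsewhere (odds ratio 258, Fisher's exact two-sided p = 2.82e-07), while 0 of 99 fell within 50 (odds ratio 0, p = 1) and 4 of 314 within 200 (odds ratio 161). A test fixed before its values were looked at, on genes that had not passed, found an unadjusted p under 0.05 for 14.5% of 193 near Trex1 and 4.55% of 12509 elsewhere (odds ratio 3.56, Fisher's exact two-sided p = 9.80e-08, and odds ratios of 3.78 within 50 and 3.17 within 200), which is consistent with linked variants; the strain of the allele is not given in the sources used here. Whether such variants alter transcripts or only the binding of probes stays open: of 2 genes with other probe sets, 1 (Alas1) had its other probe set under 0.5 of the difference, while the others of Parp3 reached 0.578 and 0.685 of it. Cmtm8 and Hemk1, a methyltransferase gene near Trex1, did not pass without a block over all arrays but did with littermate pairs as one, Cmtm8 lower and Hemk1 higher by 1.14 (limma adjusted p = 0.0996, 0.0415 with the block and 0.00224 without Trex1 WT B).

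MHC class II genes, Cd163 and Retnla, products of macrophages, had lower values together. Fewer macrophages as the whole cause was weighed with the other 23 monocyte and macrophage markers, whose median was 0.25. It lay 0.92 above that of the class II list (permutation p = 3.00e-05 over genes, which are not independent). The class II list was taken up because it was low, and Cd163, also low, was left out of the markers. A gap of this sign was therefore partly fixed in advance. Marker transcripts can also change without a change in cell number, so this comparison does not decide the question. With an estimated correlation neither full list passed (limma camera adjusted p = 0.553 for the macrophage markers and 0.306 for class II). The median of the full macrophage list was 0.075 without Trex1 KO B. A shift between macrophage types may be involved, and on 2 lists written before their values were looked at, the 14 other resident macrophage markers had a median of -0.073 (camera in limma, p = 0.736), and the 7 other inflammatory monocyte markers one of 0.33, with 6 above 0 (p = 0.00525 with the preset correlation and p = 0.123 with an estimated one). The inflammatory monocyte list left out 4 markers, Plac8, Ms4a4c, Ms4a6b and Fcgr1. Their differences were 2.81, 1.63, 1.18 and 0.73, and of these only Plac8 passed without the block. Neither list settles the question. RNA quality also stays open here. The genes' median in pair C was 0.689 of the mean of pairs A and B. The 95% interval over resampled genes, which are not independent, ran from -0.182 to 0.826. The class II median was -0.15 with the Actb ratio as a covariate (camera in limma, adjusted p = 0.912).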
